A study of Mus musculus with 2 samples.

How the data were processed

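Hi-C was made from frozen cortex of the operated side with an Arima kit, per the labels' protocols, from 3 cortices in each group. Whether these were pooled, and at which step, is not stated beyond the labels. HiC-Pro and Bowtie2 were used with the mouse build mm10, per the submitters' processing notes, which give no versions. The loop caller and its settings are not given in the sources used here. Each group has 1 deposited loop list, and the groups were taken from the sample titles.

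The counts of PETs per loop and of reads per anchor are whole numbers that the authors deposited without scaling for depth. The signal value called density was deposited by the authors as PETs per kb of anchor per 1000000 PETs, a reading that was checked on each loop, since it gave the same library total for every loop of a file. These totals are the depth used here, 34974213 PETs for sham and 40550536 for MCAO. The enrichment ratio and the ratio called P2LL are the authors' own values, and their definitions are not given in the sources used here. The p-values and the FDR are the authors' deposited values per loop, and the FDR reached 0.05 at most in both lists. Such values were used only to describe or rank loops within a list. Only loops with at least 10 PETs are listed in the deposited files, so a loop that is not listed may lie just below that minimum in a library.

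Distances were taken between anchor midpoints. A loop was called shared when a loop of the other list had both midpoints within 1 anchor width, using the wider loop. The level by chance was found by moving a list by 2 to 5 Mb in either direction (8 shifts). Shares have exact Clopper-Pearson intervals, ratios of loop numbers have exact binomial intervals, and medians have intervals from 10000 resamples of loops. PETs are not shown to be independent molecules, so all intervals and floors cover counting error only. With 1 library per group no test between conditions was made and no p-value is given.

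Gene positions came from a RefSeq table of protein-coding genes on GRCm38.p6, the assembly of mm10, with 21883 genes. The table gives no strand. The design fixed before the data were examined called for transcription starts, and loops within 2.5 kb of either end of a gene were used instead. The motif of the insulator protein CTCF was planned for anchors and was not analysed here, since no genome sequence was used. For 19 gene lists, also fixed before the data were examined, the log2 ratio of gene-loop pairs with 1 added to each sum was set against that of all genes. Its percentile was found among 10000 random lists of the same size matched on loop number, as a description of these libraries. Neighbouring genes share loops, so distinct loops are given where this matters.

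The genes named are members of the fixed lists with a loop, the 10 genes with the largest difference in each direction, and the genes at the 5 loops per library that ranked first by the authors' hypergeometric p-value among those found in a single list. Ties were broken by the smaller number in the other library and then by symbol. Some genes that this rule selects are not reported here. Jun and the protocadherin cluster were chosen for maps after their values were seen. For the number of genes with a difference of at least 5, unshared gene-end loops were divided at random between the lists as whole loops, with the number per list kept. This division was chosen after a freer one, of all loops of each gene, had given larger numbers than those found, since it ignored that shared loops stand in both lists.

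Gene density was counted in windows of 1 Mb, placed by the midpoint of each loop and divided into 4 groups by number of genes. For depth, MCAO PETs were drawn at random to the sham total and loops of at least 10 PETs were kept; the other filters of the authors could not be applied again. For coverage, PETs were drawn in the same way by the median ratio of anchor reads of shared loops in each group of windows. For span, sham loops were also reweighted to the MCAO distribution of genes per window or of anchor width in 50 groups. The matching and the list percentiles were tested on simulated data. With 14779 simulated loops, 100% of kept loops and 3.26% of moved loops were matched. Kept loops were displaced by less than the 1 anchor width that the rule allows, so the 100% was fixed by the simulation. It does not show how many true partners the rule misses in the real lists. Of 200 unchanged lists of 15 genes 4% lay outside the central 95%, and of 20 lists with a 3-fold change 95% lay above percentile 97.5.

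Alternatives covered the rule for shared loops, the better part of each list (loops on the better side of its median hypergeometric p-value), lists of equal length, loops of at least 100 kb, autosomes, the window at gene ends and the matching of random lists. A minimum of 15 PETs, thinning, overlapping anchors, the whole gene, gene density matching and distinct loops were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.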

Results

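Chromatin loops were mapped by Hi-C, which joins and sequences DNA segments lying close together in the nucleus, in the cerebral cortex of mice after experimental stroke or sham surgery. In the stroke group a filament closed the middle cerebral artery for 1 h (middle cerebral artery occlusion, MCAO), and the cortex on the operated side was collected after 6 h of reperfusion. Sham animals had the same surgery without the occlusion. The labels mention 3 cortices per group, and 1 loop list per group was analysed, so no difference given here has a replicate check and no test between conditions was made. Each list gives pairs of anchors and the number of paired-end tags (PETs) that join them. The sham library held 34974213 PETs and the MCAO library 40550536, a depth ratio of 1.16. All intervals are 95% intervals and cover counting error only.

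The comparison of MCAO with sham asks which loops differ in the cortex after stroke. More loops were listed in MCAO at Jun, an immediate early transcription factor gene (2 in sham and 8 in MCAO), and at Sema6d, an axon guidance gene (2 and 9). Heat shock and chaperone genes had 6 distinct loops in sham and 15 in MCAO, and astrocyte marker genes 12 and 25, each inside the central 95% of random gene lists as reported here and outside it in 2 of 13 settings. Fewer loops were listed in MCAO at Alcam, a cell adhesion gene (14 and 5), at B3galt2, a galactosyltransferase gene (11 and 2), and on the X chromosome (268 and 208). The numbers of genes with such differences lay inside the range that a random division of unshared loops between the lists gave, as set out with the gene values. With at least 15 PETs per loop the differences, MCAO minus sham, were 3 at Jun, 5 at Sema6d, -5 at Alcam and -2 at B3galt2.

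The sham list held 14779 loops and the MCAO list 15592, a ratio of 1.06 (1.03 to 1.08). Per 1000000 PETs, the sham library had 423 loops and the MCAO library 385. After the MCAO PETs were thinned to the sham depth, with loops of at least 10 PETs kept, the ratio was 0.770 (0.751 to 0.789), so the direction of this difference turned with depth. Both lists began at 10 PETs per loop. Loops with 10 or 11 PETs made up 42.2% of the sham list and 37.7% of the MCAO list.

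Loops were shorter in the MCAO list as a whole. The median distance between anchor midpoints was 377 kb (369 to 384) in sham and 309 kb (302 to 317) in MCAO, a ratio of 0.822 (0.796 to 0.848). Loops over 1 Mb made up 11.5% of the sham list and 9.20% of the MCAO list. Among loops found in both lists the medians were 466 kb in sham and 466 kb in MCAO. The anchors of such loops are near each other by the matching itself, so their medians are close by construction. Among loops found in a single list the medians were 355 kb in sham and 275 kb in MCAO. Anchors were also narrower in MCAO, with a median width of 20.7 kb against 24.8 kb. Among the narrowest anchors the span ratio was 1.09 (1.04 to 1.14), and with sham loops reweighted to the MCAO anchor widths it was 0.976 (0.948 to 1.00).

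Most loops of each list had no partner in the other list. With both anchor midpoints within 1 anchor width, 3785 sham loops were shared, 25.6% (24.9 to 26.3), as were 3885 MCAO loops, 24.9% (24.2 to 25.6). Lists moved along the chromosome by 2 to 5 Mb shared 2.71% and 2.60%. The share grew with the number of PETs, from 12.3% of sham loops with 10 or 11 PETs to 89.8% (86.0 to 92.9) of those with at least 51. In the MCAO list it went from 12.3% to 78.7% (73.5 to 83.3). The distance allowed for a partner grows with anchor width, and lists were moved as a whole and not by number of PETs. How much of the rise comes from the matching rule was thus not tested. Loops found in a single list had a median of 12 PETs in both libraries, near the minimum of 10, where a loop that is not listed is not shown to be absent.

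**Figure D1:**
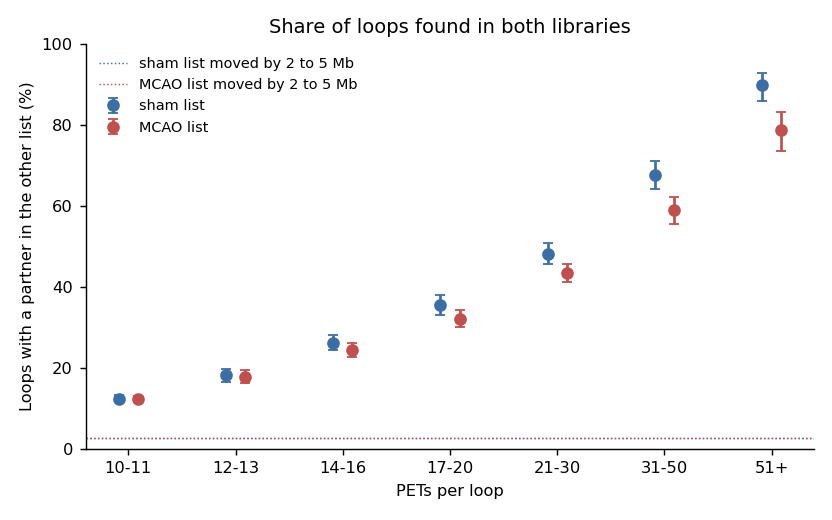
Share of loops (percent, vertical axis) with a partner in the other list, by PETs per loop (horizontal axis), for sham in blue and MCAO in red. Points are shares with exact 95% intervals, and the sham share runs from 12.3% to 89.8%. Dotted lines are the shares for whole lists moved by 2 to 5 Mb (2.71% and 2.60%), not found separately by number of PETs.

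PET numbers of single shared loops varied between the libraries in both directions. Over the 3554 pairs that were each other's nearest partner, the median log2 ratio of PETs per 1000000, MCAO over sham, was -0.21, with lower and upper quartiles of -0.80 and 0.37. The median ratio of unscaled PETs was 0 on the log2 scale, so the offset has the size of the depth scaling. The PET numbers of the pairs correlated weakly (Spearman's rho 0.20, across loops, which are not replicates). Both lists began at 10 PETs, and shared loops had a median of 17 PETs in sham and 18 in MCAO. This narrow range near the minimum may weaken the correlation.

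Loops of the MCAO library lay more often at genes. An anchor lay within 2.5 kb of an end of a protein-coding gene in 61.3% (60.5 to 62.1) of MCAO loops and 52.5% (51.7 to 53.3) of sham loops, against 41.0% and 40.3% for moved lists. Among shared loops, whose anchors are near each other by the matching itself, the shares were 69.3% (67.9 to 70.8) in MCAO and 70.4% (68.9 to 71.8) in sham. Among loops found in a single list the shares were 58.6% (57.7 to 59.5) in MCAO and 46.4% (45.4 to 47.3) in sham. Of 21883 genes, 6389 had a loop in both lists, 4083 in MCAO only, 3014 in sham only and 8397 in neither. The gap was widest in gene-poor regions: in windows of 1 Mb with 0 to 2 genes, 36.8% (35.3 to 38.2) of MCAO loops and 27.9% (26.7 to 29.1) of sham loops reached a gene end. In windows with 12 to 67 genes the shares were 84.6% (83.4 to 85.6) and 83.5% (82.1 to 84.8).

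Gene-rich chromosomes had relatively more loops in MCAO. Chromosome 7 went from 638 loops in sham to 837 in MCAO, a ratio of 1.31 (1.18 to 1.46), chromosome 19 from 297 to 376 (1.27, 1.08 to 1.48) and chromosome 11 from 738 to 916 (1.24, 1.13 to 1.37). More loops were listed in MCAO on 12 autosomes and fewer on 7, while per PET it was more on 3 and fewer on 16. The X chromosome had a ratio of 0.776 (0.644 to 0.934). Across the 19 autosomes the log2 ratio followed the number of genes per Mb (Pearson's r 0.858, Spearman's rho 0.784), and without the 2 chromosomes farthest from the median density r was 0.762. These are chromosomes of a single pair of libraries and not replicates. In windows of 1 Mb the loop ratio was 0.802 (0.771 to 0.835) with 0 to 2 genes, 1.06 with 3 to 5, 1.16 with 6 to 11 and 1.39 (1.33 to 1.46) with 12 to 67. The densest windows exceeded the sparsest by 0.79 (0.70 to 0.88) on the log2 scale. Read density at the anchors of shared loops was shifted the same way, with a median log2 ratio of -0.15 in the sparsest windows and 0.07 in the densest. After PETs were thinned by this coverage gap, the loop difference was 0.31 (0.21 to 0.41) with 1 anchor counted and -0.16 (-0.27 to -0.05) with both, where its direction turned.

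**Figure D2:**
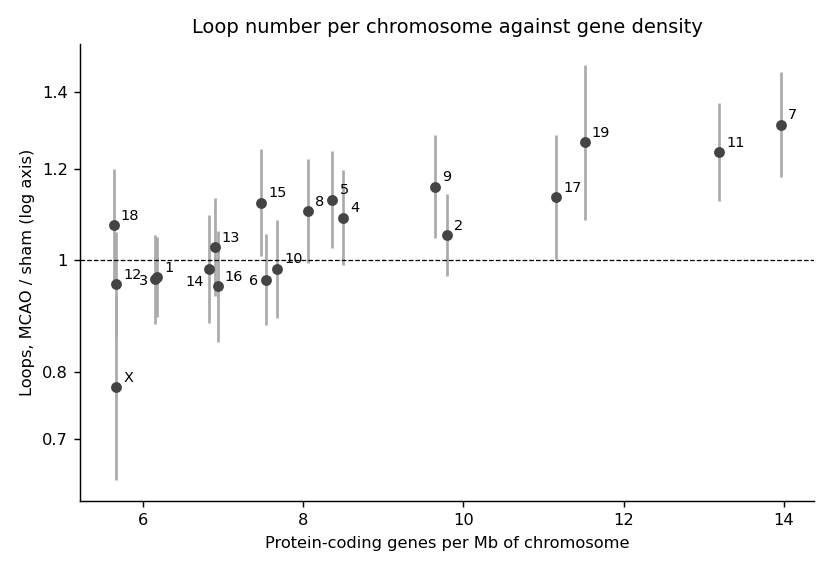
Ratio of loop numbers, MCAO over sham (vertical log axis), against protein-coding genes per Mb (horizontal axis), with 1 point per chromosome and exact 95% intervals as lines. Chromosome 7 is highest at 1.31 and X lowest at 0.776; Y, with a single loop, is not drawn.

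With all loops as listed, gene ends within 2.5 kb and random lists matched on loop number, each of the stress and injury lists lay inside the central 95%. The heat shock and chaperone list had 6 gene-loop pairs in sham and 16 in MCAO, with more at 7 genes and fewer at 2. Dnajb1, a co-chaperone gene, had 2 and 5 loops, Bag3 0 and 2, the small heat shock gene Cryab 0 and 2, and Hspa1b 2 and 1. The shift of this list against all genes was 1.00 on the log2 scale, at percentile 97.0 among 10000 random lists and 71.8 to 98.5 over all settings, outside the central 95% in 2 of 13. Immediate early genes had 29 pairs in sham and 41 in MCAO, with more at 10 genes and fewer at 3 (percentile 79.8). Besides Jun, Ier3 had 1 and 4 loops and Egr2 2 and 4, while the nuclear receptor gene Nr4a3 had 3 and 0 and Fosb 2 and 0. Fos itself had 1 and 1. Hypoxia response genes had 10 and 16 pairs (percentile 76.1, and 23.1 to 99.5 over all settings, outside the central 95% in 1 of 13), with more at 8 genes and fewer at 4. Hif1a had 0 and 2 and the glucose transporter gene Slc2a1 1 and 3, while Pdk1 had 2 and 0 and Ldha, Ndrg1 and Car9 each 1 and 0. Inflammatory mediators had 15 and 14 (percentile 22.3; more at 6 genes, fewer at 6), with 4 and 2 at the cyclooxygenase gene Ptgs2, 0 and 2 at Nos2 and none in either list at Il1b, Il6 or Tnf. Cell death genes had 17 and 21 (percentile 52.9), with more at 6 genes and fewer at 5, such as 1 and 4 at Cdkn1a and 2 and 0 at Casp8. Antioxidant genes had 8 and 10 (percentile 52.8), with more at 5 genes and fewer at 2. All genes together had 15296 pairs in sham and 18573 in MCAO, a log2 ratio of 0.28.

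Among cell type markers, astrocyte genes had 12 pairs in sham and 25 in MCAO, with more at 6 genes and fewer at 1 (percentile 97.0, and 60.2 to 98.1 over all settings, outside the central 95% in 2 of 13). The glutamate transporter gene Slc1a3 had 2 and 7 loops, a difference that was 0 with at least 15 PETs per loop and 2 after thinning to the sham depth, the transcription factor gene Sox9 3 and 6, and the glutamine synthetase gene Glul 1 and 4. Excitatory neuron markers had 22 and 33 (percentile 86.2), with more at 6 genes and fewer at 2: 3 and 7 at Bcl11b and 1 and 5 at Cux2, both genes of cortical projection neurons, and 3 and 2 at Rorb and Foxp2. Inhibitory neuron markers had 11 and 9 (percentile 15.6), with more at 2 genes (Dlx5 2 and 3, Dlx6 1 and 2) and fewer at 2, the glutamate decarboxylase genes Gad1 (3 and 0) and Gad2 (3 and 2). Oligodendrocyte lineage markers had 13 and 11 (percentile 20.8), with 3 and 0 at the myelin gene Mbp, 1 and 0 at Olig2, 0 and 1 at Cspg4 and 6 and 6 at Pdgfra. Microglia markers had 4 and 8 (percentile 80.2), endothelial and mural markers 7 and 4 (percentile 10.5) and neutrophil and blood leukocyte markers 4 and 6 (percentile 61.9). Glutamate receptor genes had 36 and 54 (percentile 89.4; more at 14 genes, fewer at 3), with 1 and 4 at Grik2 and 8 and 4 at Grm3. Synaptic genes had 29 and 41 (percentile 77.7; more at 9 genes, fewer at 4), with 0 and 3 at Snap25 and 5 and 4 at Bdnf. Genes of chromatin architecture had 12 and 11 (percentile 22.0), with fewer at 4 genes, among them Ctcf with 2 and 0, and more at 3, Mau2 (0 and 2), Smc3 (1 and 2) and Stag2 (2 and 3). Housekeeping genes had 12 and 15 (percentile 50.7).

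**Figure D3:**
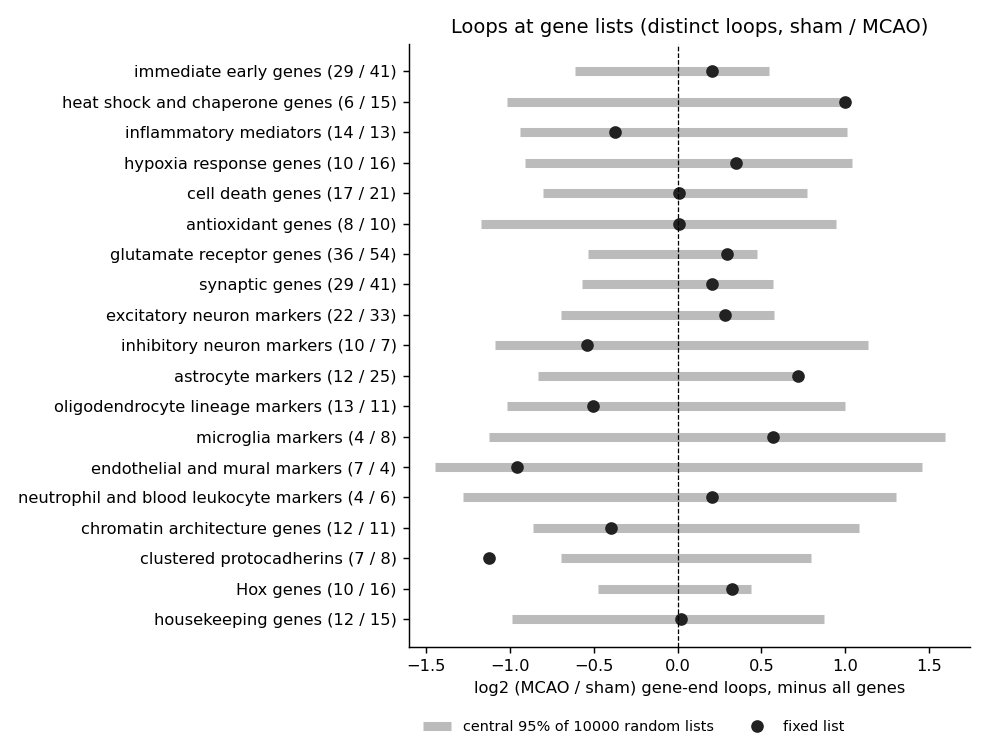
Log2 ratio of gene-end loops, MCAO over sham, minus that of all genes (horizontal axis), for the 19 fixed lists, with the central 95% of 10000 random lists as grey bars and the distinct loops of sham and MCAO beside each name. Clustered protocadherins, at -1.13, are the single list outside its bar, while their distinct loops were 7 and 8. That list holds no Pcdhg genes other than Pcdhgc3, Pcdhgc4 and Pcdhgc5.

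At Jun (chromosome 4, 95049036 to 95052222, mm10) the sham list held 2 loops and the MCAO list 8. Both sham loops had a partner in MCAO: the nearer, 105 kb long, carried 15 PETs in sham and 17 in MCAO, and the farther, with a span of 811 kb in sham, carried 25 and 23. The MCAO loop with the most PETs at Jun, 28, had its far anchor at 95553159 to 95571427 and no partner in sham. The remaining MCAO loops at Jun carried 11 to 21 PETs. The interval of the difference of 6 loops ran from -1.12 to 9.50 and held 0.

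**Figure D4:**
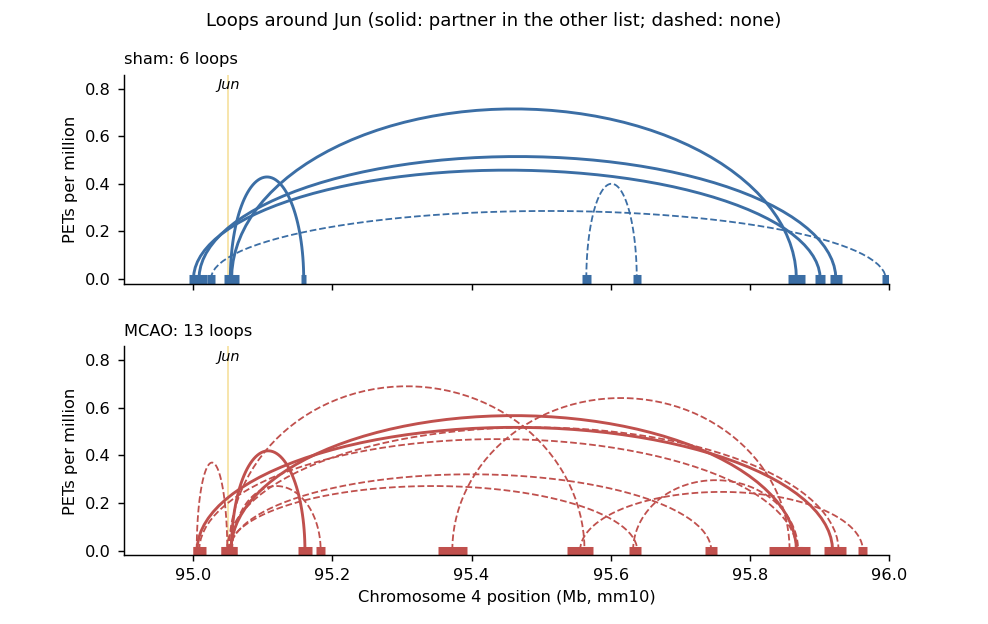
Loops around Jun on chromosome 4 (position in Mb, horizontal axis; height in PETs per 1000000), sham above and MCAO below, with anchors as bars and solid arcs for loops with a partner in the other list. The region drawn holds 6 sham loops and 13 MCAO loops, and the yellow line marks Jun.

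Clustered protocadherins, adhesion genes of neuronal identity that lie side by side on chromosome 18, had 7 distinct loops in sham and 8 in MCAO. The list held the Pcdha and Pcdhb genes but, of the Pcdhg genes, only Pcdhgc3, Pcdhgc4 and Pcdhgc5. Loops at other Pcdhg genes were thus not counted. Both libraries had anchors between the listed Pcdhb and Pcdhgc genes, such as 37687438 to 37708682 in sham and 37757898 to 37769406 in MCAO. Counted at every listed gene, the list had 35 gene-loop pairs in sham and 19 in MCAO, a shift of -1.13 at percentile 0.08. A single sham anchor, 37172950 to 37231112, covered the end that the Pcdha genes share. Its loop had a partner in MCAO, whose anchor ended at 37166396, short of that shared end. The random lists were drawn without regard to neighbours, so their range may be too narrow for genes that share loops. With any part of the gene counted the shift was 0.23, and in the better part of each list by the authors' p-value it was -0.03, while with at least 15 PETs it was -2.59. The list lay outside the central 95% in 10 of 13 settings. In sham, loops joined anchors within the Pcdhb genes to a region beyond the Pcdhgc genes, such as 37407412 to 37452931 with 37847868 to 37908285 (27 PETs). These had no partner in MCAO. The MCAO list held a loop between 36998273 to 37030315, among the Pcdha genes, and 37211227 to 37226741 (32 PETs), which had no partner in sham.

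**Figure D5:**
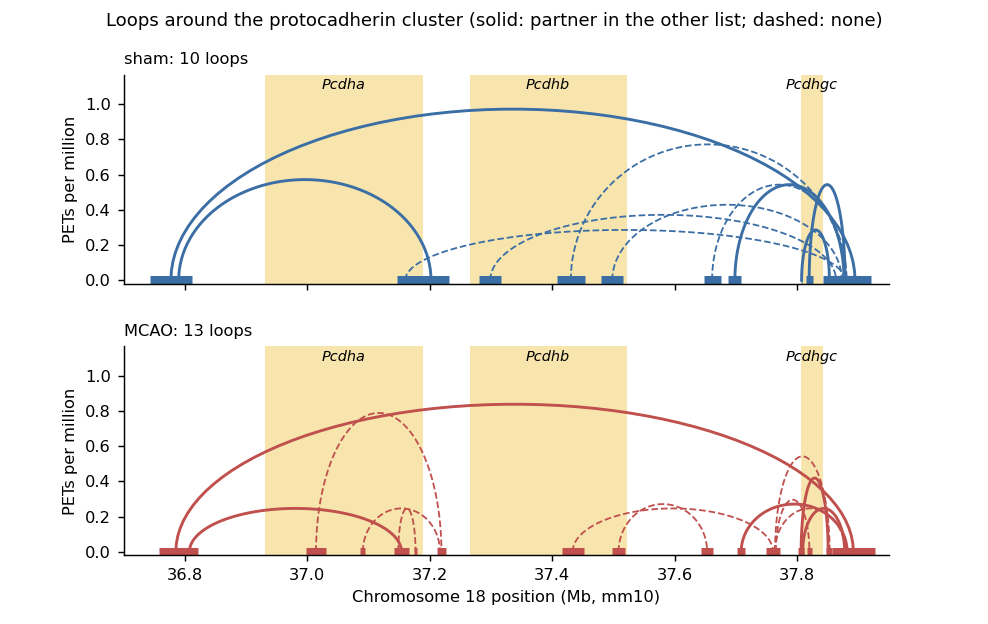
Loops around the protocadherin cluster on chromosome 18 (position in Mb, horizontal axis; height in PETs per 1000000), sham above and MCAO below, with anchors as bars, solid arcs for loops with a partner in the other list and gene groups in yellow. The region drawn holds 10 sham loops and 13 MCAO loops, 5 with a partner in each.

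Among gene-end loops within 2.5 kb, the axon guidance gene Sema6d (chromosome 2, 124089943 to 124667789) had the largest excess in MCAO, with 2 loops in sham and 9 in MCAO and 250 PETs in its MCAO loops. With any part of the gene counted its difference was 2, against 10 at Nedd4l, and with a window of 10 kb it was 6, against 7 at Add3. The DNA repair endonuclease gene Ercc4, the cytokine gene Il17b, the ubiquitin ligase gene Nedd4l, Rasgef1b and Tmeff1 each had 0 loops in sham and 6 in MCAO. The metalloprotease gene Adamts17, the membrane skeleton gene Add3 and Sipa1l3 each had 1 and 7. The neurturin receptor gene Gfra2 had 2 and 8. Of these, Nedd4l, Il17b and Tmeff1 had no MCAO loop with a partner in sham, while Ercc4 and Rasgef1b had 1 each and Gfra2 had 2. With a window of 10 kb the difference was 4 at Ercc4 (-3.05 to 8.67) and 5 at Rasgef1b (-1.10 to 6.95), and both intervals held 0. At Il17b, Nedd4l and Tmeff1 the difference stayed at 6 with that window. With no window it was 6 at Il17b and Tmeff1, 5 at Rasgef1b and 3 at Nedd4l and Ercc4. The intervals at Rasgef1b, Nedd4l and Ercc4 then held 0. In the better part of each list the difference was 3 at Rasgef1b, 2 at Il17b, Nedd4l and Ercc4 and 0 at Tmeff1. With at least 15 PETs per loop the difference was 5 at Sema6d, 3 at Il17b and Rasgef1b, 2 at Ercc4, Nedd4l and Gfra2, 1 at Tmeff1, Add3 and Sipa1l3 and 0 at Adamts17. The interval of the difference of 7 loops at Sema6d ran from -0.391 to 10.5 and held 0. Those at Adamts17, Add3, Sipa1l3 and Gfra2 held 0 as well, while those of the genes without a loop in sham began at 0.489. All these genes were chosen by the size of the same difference, so an interval without 0 does not set a gene apart.

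With gene ends within 2.5 kb, the largest excess in sham was at B3galt2 (chromosome 1, 143640697 to 143649937), with 11 loops in sham and 2 in MCAO, and at Alcam (chromosome 16, 52248996 to 52453081), with 14 and 5. With any part of the gene counted the difference was -9 at B3galt2 and -7 at Alcam, against -10 at Samd12. With a window of 10 kb it was -8 at B3galt2 (-12.7 to 0.223) and at Alcam (-15.2 to 1.71), and both intervals held 0. The mitochondrial genes Yars2, for a tRNA synthetase, and Dnm1l, for a fission protein, are neighbours on chromosome 16 and had 6 loops each in sham with the same 131 PETs in total, against 0 and 1 in MCAO. The scaffold gene Lin7c had 7 and 1. The ubiquitin ligase gene Fbxw7 and Samd12 each had 5 and 0, and Fbxo33 and Gnpda2 each had 6 and 1. With at least 15 PETs per loop the difference was -5 at Alcam, -4 at Yars2 and Dnm1l, -3 at Fbxo33 and Gnpda2, -2 at B3galt2, Fbxw7 and Samd12 and -1 at Lin7c. The interval of the difference at Alcam ran from -15.5 to 0.457 and held 0. All others named here did so too, except those at B3galt2 (-12.5 to -1.18) and Yars2 (-6 to -0.489). Here too the genes were chosen by the size of the difference, so an interval without 0 does not set a gene apart.

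MCAO had at least 5 more loops than sham at 51 genes and at least 5 fewer at 15. When shared loops were kept in their lists and the other gene-end loops were divided at random 1000 times, 43.7 genes on average (31 to 57.0) had at least 5 more and 10.7 (4 to 18) at least 5 fewer. Both numbers lay inside these central 95% ranges. Dividing loops only among windows with the same number of genes gave 41.4 (30.0 to 56) and 12.6 (6 to 20).

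The loops that ranked first by the authors' p-value among those without a partner within 1 anchor width joined broad anchors, such as 3454788 to 3564107 on chromosome 18 at Bambi. In sham they joined Bambi with Lyzl1 (100 PETs), a region of chromosome 2 with the neurotrophin gene Bdnf (99 PETs), and Tgfbr1, Alg2 and Sec61b with Nr4a3 and Stx17 (96 PETs), followed by loops of Aff3 with Lonrf2 (73 PETs) and at Itgb6 and Rbms1 (77 PETs). In MCAO they joined Uaca with Rplp1 and Kif23 (116 PETs), Vps13c with a region inside Rora (105 PETs) and Zbtb20 with Tigit (110 PETs), and lay at Zmat3 (76 PETs) and Chsy3 (104 PETs). Both anchors of the loop of Zbtb20 and Tigit lay over Zbtb20. The nearest loop of the other list lay from 92.9 kb, at Zmat3, to 454 kb, at Itgb6, away. With 2 anchor widths allowed, 7 of these 10 loops had a partner, and the sham loop nearest to that at Chsy3 carried 125 PETs. The authors' P2LL ratio, whose definition is not given in the sources used here, was 1.28 to 3.03 for these loops, against a median of 5.50 in each list.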

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

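The minimum of 15 PETs, thinning, overlapping anchors, the whole gene, matching on gene density and distinct loops were chosen after seeing the data. The higher share of gene-end loops in MCAO and its shorter spans kept their direction in the settings of filter, list length and depth, with span ratios from 0.768 to 0.908. The span ratio was 1.09 among the narrowest anchors and 0.976 with anchor widths reweighted. The loop number did not: it was 0.770 after MCAO was thinned to the sham depth, 1.18 with at least 15 PETs, and 1 by construction for lists of equal length. The cause was not tested beyond the settings themselves. Of the loops with 10 or 11 PETs, 12.3% had a partner in sham and in MCAO alike, and depth as a cause of this low share was not tested. CTCF motifs and their alternatives were not run, and identical anchors gave no pairs for loop strength. No paired analysis was possible because each group has 1 library.

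In the better part of each list the span ratio was 0.908, the shared shares 30.2% of sham and 29.1% of MCAO, the gene-end shares 59.3% of sham, 53.0% of sham-only, 67.4% of MCAO and 65.6% of MCAO-only loops, and 2 gene lists lay outside the central 95%, hypoxia response genes (percentile 99.5) and Hox genes (98.5), while protocadherins were at 51.1. For lists of equal length the span ratio was 0.768. With loops of at least 100 kb it was 0.862, and the shared shares were 27.9% and 27.7%. Identical anchors gave shared shares of 0 and 0, so that the loops of a single list were all loops, with gene-end shares of 52.5% and 61.3%. Within 2 anchor widths the shared shares were 38.0% and 37.1% and the sham-only gene-end share 44.5%. Within 25 kb the shared shares were 22.6% and 21.9%, and with overlapping anchors 23.1% and 22.3%.

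With no window at gene ends the gene-end shares were 48.3% of sham, 42.4% of sham-only, 56.1% of MCAO and 53.2% of MCAO-only loops, with 2 lists outside, protocadherins and heat shock genes. With a window of 10 kb they were 59.6%, 53.4%, 68.8% and 66.2%, with 0 lists outside. For any part of the gene they were 77.2%, 73.2%, 83.0% and 81.3%, with 0 lists outside, and the protocadherin shift turned to 0.23. With at least 15 PETs they were 63.2%, 57.2%, 70.5% and 69.0%, and the shared shares 32.6% and 28.1%. With MCAO thinned, the span ratio was 0.883, the shared shares 22.6% and 29.4%, the gene-end shares 64.3% of MCAO and 61.4% of MCAO-only loops, and 4 lists lay outside: protocadherins, Hox genes, heat shock genes and astrocyte markers. With random lists matched also on gene density 2 lay outside, protocadherins and astrocyte markers. The log2 difference in loop ratio between the most and least gene-dense windows was 0.31 after PETs were thinned by the coverage gap, and -0.16 with both anchors counted.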

Other observations

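The tests of the coverage gap at both anchors, of span after reweighting and of the gene density of the X chromosome were chosen after the result was seen. Hox genes, the clustered regulators of body axis identity, had 10 distinct loops in sham and 16 in MCAO, and 45 and 69 gene-loop pairs at percentile 92.9 of random lists. In the Hoxc cluster on chromosome 15 the sham list had no loop at any gene, while the MCAO list had 4 at Hoxc4, 3 at Hoxc6, 2 at Hoxc5 and 1 each at Hoxc8, Hoxc9, Hoxc12 and Hoxc13. In the Hoxa cluster Hoxa13 had 4 loops in sham and 2 in MCAO. Hoxd9 had 2 and 6. Neighbouring Hox genes share loops.

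The loop ratio was higher in gene-dense than in gene-poor windows, by 0.79 (0.70 to 0.88) on the log2 scale. The difference was 0.76 after the PETs of listed MCAO loops were thinned to the sham depth (0.73 to 0.79 over 20 draws). Loss of listed loops to the minimum of PETs thus does not account for it. Loops were not called again and the authors' other filters were not applied again. Whether depth acted through those filters cannot be told from this thinning. Anchor read density at shared loops differed the same way by 0.22 (0.19 to 0.25), which lay between the bounds set beforehand for and against coverage as the cause. Thinning PETs by this gap left 0.31 (0.21 to 0.41) when applied for 1 anchor and -0.16 (-0.27 to -0.05) when applied for both. The rule for coverage at both anchors asked for an interval that included no difference. It was unmet, so this test cannot tell. The direction turned between the settings, so uneven coverage as the whole cause is not excluded. With 1 library per group, coverage and an effect of the occlusion on looping in gene-dense chromatin cannot be told apart. Depth acting through the authors' other filters stays open too.

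The span ratio of MCAO over sham loops was 0.822, and thinning the PETs of listed MCAO loops to the sham depth left 0.884. Loss of listed loops to the minimum of PETs is thus not the whole cause. The authors' other filters were not applied again, so depth acting through them was not tested. Within 4 groups of anchor width the ratios were 1.09, 0.963, 0.932 and 0.979, from narrow to broad, and sham loops reweighted to the MCAO anchor widths gave 0.976 (0.948 to 1.00), so narrower anchors may carry the difference, though longer loops also had broader anchors. Within 4 groups of gene density they were 0.952, 0.951, 0.877 and 0.849, from poor to dense, so the 2 sparser groups missed the bound set beforehand, every group under 0.95. By the reweighting to the MCAO gene counts, 0.915 (0.889 to 0.940), and a rule changed after the values were seen, the shift towards gene-dense regions is not the whole cause. Depth and gene density were not applied together, so whether both jointly leave a difference was not tested. Their joint action, depth acting through the authors' other filters, anchor width and an effect of the occlusion, which was not tested, stay open.

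The X chromosome had 268 loops in sham and 208 in MCAO, a ratio of 0.776 (0.644 to 0.934). Its low gene density does not account for this, since autosomal windows of the same gene density gave 1.06. Anchor read density at shared loops, X over autosomes, was 0.519 in sham and 0.455 in MCAO, a ratio of 0.876 (0.847 to 0.914) over 52 pairs. A different share of male and female animals in the libraries could lower it, and the interval spans the bound of 10% set beforehand, so this stays open, as does an effect of the occlusion. Single X-linked genes went both ways, with 1 loop in sham and 0 in MCAO at Syn1 and Smc1a, 2 and 3 at Stag2 and 0 and 1 at Pgk1.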
